A study of Rattus norvegicus with 6 samples.

How the data were processed

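Total RNA was extracted from liver with Trizol, and biotin-labelled cRNA was prepared from 8 ug of it and hybridised to 1-colour Affymetrix arrays, per the labels' protocols. The authors deposited 1 intensity per probe set and array on a linear scale. The software that made these intensities and its settings are not given in the sources used here. The values show how they were scaled: the mean after removing the top and bottom 2% of probe sets was 500 on every array, as a linear global scaling gives. Such scaling does not equalise the shape of the distributions, and the median of log2(intensity + 16) ranged from 6.729 to 7.348 between arrays. This range was above the limit of 0.2 set before the data were examined, so the log2 values were quantile normalized. Quantile normalization removes any difference between groups in the overall distribution of signals. Median centring and no further normalization were run as alternatives, and the median difference over the probe sets tested was 0.00416 with quantile normalization, 0.0292 with median centring and -0.0197 without normalization.

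The 3 probiotic and 3 high-fat samples were grouped by their titles. The table held 31099 probe sets. The 57 control probe sets were left out of the test. Gene names came from the platform annotation, which dates from earlier than the reference, and symbols were updated through gene identifiers to the rat RefSeq table of assembly GRCr8. Of 20832 probe sets listed with 1 symbol, 20764 matched, and 0 symbols changed. Among the probe sets other than controls, 20826 had 1 symbol, 436 had several and were not named, and 9780 are unnamed here. No genome coordinates were used. Probe sets with a mean of at least the 40th percentile over the 6 arrays were tested, which left 18625 probe sets for 10573 genes. A fold is the difference on the log2(intensity + 16) scale and understates changes of dim probe sets.

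Groups were compared with limma 3.58.1 in R 4.3.3 by lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. All differences are probiotic minus high-fat. Of 30 gene lists fixed before the data were examined, 29 had at least 5 measured genes. Pancreatic acinar markers had fewer and were not tested. Lists were tested with camera at a preset correlation of 0.01 on the brightest probe set of each gene, adjusted over the 29 lists, and again with an estimated correlation and with fry. RNA quality was read from the 3' and 5' control probe sets of Actb and Gapdh and compared by an exact permutation test.

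Named genes were chosen by a rule set before the data were examined. It took up to 10 genes in each direction with 1 symbol, no overlap between groups and the smallest p, since none passed the adjusted threshold, then the 4 members of smallest p from every list past the threshold, and a fixed set of cholesterol, bile acid and lipid genes. Some genes of the fixed set are not reported here. A gene is given by its brightest probe set, or under the rule by p by the probe set that met it.

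The scripts were tested on simulated data with 200 of 18625 probe sets changed and the fitted spread, in 20 runs. For this comparison the test recovered 0.8% of probe sets changed 1.5-fold, 8.6% of those changed 2-fold, 54.1% of those changed 4-fold and 76% of those changed 8-fold, with 3 false calls per run. A list shifted 1.5-fold was found in 20 of 20 runs, in data simulated without correlation between genes. Alternatives covered the normalization, the signal filter, the pseudocount (1 and 64), the variance model, array weights, the replicate number as a block, a plain t-test, the set test and each sample left out in turn. Added after seeing the data were no normalization between arrays, the Actb gap as a covariate, and leaving out both high-fat sample 2 and probiotic sample 2. Figures were drawn with matplotlib 3.10.9.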

Results

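Liver gene expression was measured on 1-colour microarrays in 6 liver samples from rats made hypercholesterolemic by feeding. Rats of both groups ate a fat-rich diet for 30 d. For the next 30 d they stayed on that diet and received 1 ml of saline daily by gavage, either plain or carrying Lactobacillus casei Zhang, a lactic acid bacterium given as a probiotic. Plain saline defined the high-fat control group and the bacterium the probiotic group, with 3 samples in each. The series describes the samples as picked at random from the groups and does not state separately that each came from its own rat. The p-values per probe set thus measure the spread between these samples. Those of the gene lists at the preset correlation of 0.01 rest on the spread over genes, taken as nearly independent. A split of the samples that mixed the groups also called 8 lists at that setting. Each array gave a signal for 31099 probe sets, with a trimmed mean of 500 on every array and a median signal between 90.05 and 146.9. Precision is limited by the number of arrays.

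The samples did not fall apart by group as a whole. Correlations between arrays were 0.9163 to 0.9533 within groups and 0.8848 to 0.9586 between groups. High-fat sample 2 and probiotic sample 2 lay at opposite ends of the leading principal component, which held 35.5% of the variance. Their scores were 75.55 and -51.6. The signal gap between the 3' and 5' probe sets of Actb, a measure of RNA integrity in which a larger gap goes with shorter transcripts, was 2.50 ± 0.459 (SD, n = 3) on the log2 scale in the probiotic group and 1.84 ± 0.213 (SD, n = 3) in the high-fat group. The exact two-sided permutation p was 0.1, the smallest that 3 samples against 3 allow. For Gapdh the gap was 1.142 ± 0.396 and 0.617 ± 0.154 (SD, n = 3 each; exact permutation p = 0.2). This difference in RNA quality accompanies every gene group described for the comparison.

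**Figure D1:**
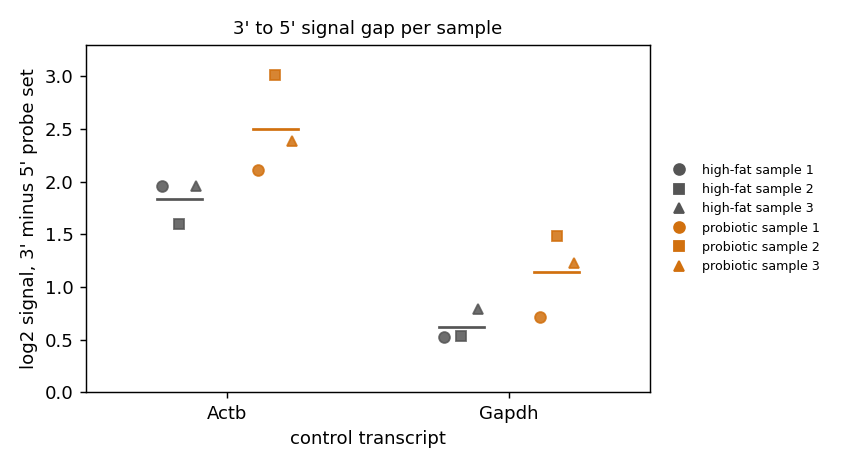
Difference in log2 signal between the 3' and 5' control probe sets of Actb and Gapdh (vertical axis) in each of the 6 samples; symbols give the sample number and short lines the mean of each group of 3. The Actb gap lay at 2.11, 3.01 and 2.38 in the probiotic samples and at 1.96, 1.59 and 1.96 in the high-fat samples.

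The comparison of the probiotic with the high-fat group addressed which liver transcripts differ after feeding L. casei Zhang on a fat-rich diet. As sets, genes of the acute phase response and inflammation and markers of Kupffer cells, the resident macrophages of the liver, were lower in the probiotic group at a preset correlation between genes (adjusted p = 0.43 for each with an estimated correlation). Genes of bile acid synthesis and transport and of fatty acid oxidation were higher as sets, by smaller amounts (adjusted p = 0.43 and 0.778 with an estimated correlation), and the call for fatty acid oxidation was lost when any of 3 samples was left out. No gene with a symbol passed the adjusted test across all probe sets, and genes of cholesterol synthesis went both ways. Of the 18625 probe sets tested with limma, 4 fell in the probiotic group and 0 rose at an adjusted p under 0.05, and all 4 are unnamed here. At an unadjusted p under 0.05 there were 1275 probe sets (6.85%), and an adjusted test of each probe set with its own variance alone called 1, which was not among these 4. The unadjusted count was 830 without probiotic sample 2, 795 without high-fat sample 2 and 443 with the Actb gap as a covariate.

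The 4 probe sets that fell differed by several log2 units, and they are named here after their values were seen. Probe set 1389990_at had a log2 signal of 8.62 ± 0.387 in the probiotic and 13.8 ± 0.255 in the high-fat group (SD, n = 3 each), a difference of -5.14 (SE 0.235, adjusted p = 4.47e-05), or 35.3-fold lower. Probe set 1370988_at was 16.1-fold lower, at 8.45 ± 0.569 against 12.5 ± 0.369 (adjusted p = 0.00242). Probe set 1392627_x_at, whose suffix marks probes that can bind other transcripts, was 8.07-fold lower, at 9.30 ± 0.353 against 12.3 ± 0.313 (adjusted p = 0.00243). Probe set 1377151_at was 16.7-fold lower, at 4.64 ± 0.448 against 8.71 ± 0.192 (adjusted p = 0.0143). Its level in the probiotic group lay near the floor that the pseudocount sets, and the fold is understated there. Its adjusted p was 0.0896 without high-fat sample 2, 0.0976 without both sample 2 arrays and 1 with the Actb gap as a covariate, and without high-fat sample 1 or 3 it was not tested, being below the signal filter. Without probiotic sample 1 the test called 12 probe sets, 6 higher and 6 lower, and without high-fat sample 1 it called 9, 1 higher and 8 lower.

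Among genes with a symbol, Ephx2 came nearest to the threshold. Ephx2, the soluble epoxide hydrolase that breaks down epoxides of fatty acids, had a log2 signal of 9.11 ± 0.287 in the probiotic and 10.99 ± 0.255 in the high-fat group (SD, n = 3 each), 3.69-fold less (SE 0.229 on the log2 scale, adjusted p = 0.0529). Of 19 other settings, 6 took it past the threshold (adjusted p of 0.0136 to 0.048, the latter without probiotic sample 1) and 13 did not, at 0.0569 to 1. With each of the other 5 samples left out it stayed above the threshold, at up to 0.515 without high-fat sample 3. The next genes by p with lower values and no overlap between groups did not pass. They were Ptprk, a receptor tyrosine phosphatase (log2 difference -2.99), RT1-A, a class I histocompatibility antigen (-2.07), Eprs1, an aminoacyl-tRNA synthetase (-2.00), the transcription factor Stat3 (-2.26), the quinone reductase Nqo1 (-1.43), the cytokine Il7 (-1.23), Fndc3b (-0.956), the death receptor Tnfrsf21 (-3.10) and the transcription factor Mef2c (-1.84). The adjusted p of Ptprk and of RT1-A was 0.281, and that of the others reached 0.688. Ptprk passed under 1 of 14 other settings (eBayes without trend, adjusted p = 0.0434), Eprs1 under 1 of 19 (without probiotic sample 1, 0.0472) and Tnfrsf21 under 1 of 19 (without high-fat sample 1, 0.0111). Under the rest their adjusted p reached 1. Another Tnfrsf21 probe set gave -3.71, another Stat3 probe set -0.979, another of Il7 -0.681 and others of Fndc3b -0.352 and -1.47. For Eprs1, 2 brighter probe sets gave only -0.36 and -0.38. For Ptprk, 2 brighter probe sets gave -0.339 and 0.149, and the one named lay near the floor in the probiotic group, at 4.845. Another Mef2c probe set gave 0.165, and the one named was dim in the probiotic group, at 5.887. RT1 genes form a family of near-identical, variable members, and the assignment of RT1-A signal to a single gene is uncertain.

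Genes with higher values in the probiotic group lay further from the threshold, at adjusted p from 0.616 to 0.726. The log2 differences were 2.41 (SE 0.448) for Hrk, an activator of apoptosis, 1.40 for the peroxisomal acyl-CoA thioesterase Acot3, 0.603 for the cytochrome P450 Cyp3a9, and 1.40 for the efflux pump Abcb1a. They were 1.49 for Tent5c, 1.04 for Fchsd2, 1.06 for the membrane progestin receptor Paqr7, 1.05 for Phf20 and 0.534 for Crot, the peroxisomal carnitine octanoyltransferase. Other probe sets gave 0.281 for Abcb1a, 0.262 for Crot and 0.58, 0.48 and 0.905 for Phf20. Tnrc6c, which acts in microRNA silencing, had a value of 1.08, and 2 of its 4 other probe sets had the opposite sign.

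**Figure D2:**
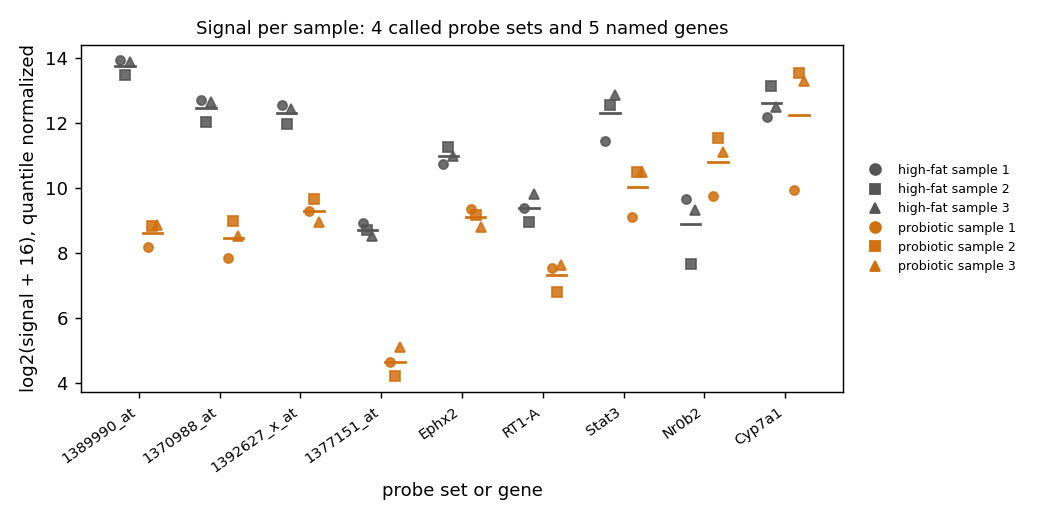
Quantile-normalized log2 signal (vertical axis, pseudocount 16) in each of the 6 samples for the 4 probe sets that fell and for 5 named genes; symbols give the sample number and short lines the group means of 3. The groups do not overlap for the 4 probe sets, Ephx2, RT1-A, Stat3 and Nr0b2. Ephx2, RT1-A and Stat3 were chosen by a rule that required this, and 12.72% of all probe sets tested did not overlap. For Nr0b2 the lowest probiotic value was 9.755 and the highest high-fat value 9.671. Cyp7a1 had group means of 12.25 in the probiotic and 12.6 in the high-fat group.

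The list of acute phase and inflammation genes fell as a set. Of its 23 measured genes, 20 were lower and 3 higher, with a mean log2 difference of -0.565 (adjusted p = 1.16e-09 with camera at the preset correlation; adjusted p = 0.43 with an estimated correlation). Adjusted over the list alone, 7 members fell, against 0 over all probe sets. They were Stat3 (-2.26), Hamp, which encodes the iron hormone hepcidin (-0.881), the cytokine Il1b (-1.47), the protease inhibitor Serpina3n (-0.443), the lipopolysaccharide-binding protein gene Lbp (-0.819), the receptor Il1r1 (-1.44) and C-reactive protein, Crp (-0.573). Several genes of plasma proteins differed less: Fgb -0.287, Orm1 -0.259, Fgg -0.157, Cp -0.153, Fga -0.152, C3 -0.139 and Hpx -0.0972. A2m had -1.65, with high-fat values spread over an SD of 2.788. The 3 higher members were Nfkbia (0.774), Hp (0.00936) and Cd14 (0.00929). Hamp had a log2 signal of 14.4 ± 0.226 in the probiotic and 15.28 ± 0.409 in the high-fat group (SD, n = 3 each). The level of the list was not high in every control: high-fat sample 1 lay at -0.229 from the mean of all samples, near the probiotic samples at -0.295, -0.31 and -0.243, and high-fat samples 2 and 3 lay at 0.684 and 0.393. Without high-fat sample 2, which stood apart from the rest, the mean difference was -0.357 (adjusted p = 1.63e-06), and with the Actb gap as a covariate it was -0.355 (adjusted p = 0.00102).

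Markers of Kupffer cells and macrophages fell as a set, with 17 of 17 measured genes lower and a mean log2 difference of -0.343 (adjusted p = 7.32e-06; adjusted p = 0.43 with an estimated correlation). No member passed on its own. The complement genes C1qc and C1qb had differences of -0.582 (SE 0.229) and -0.606 (SE 0.304), the macrophage growth factor receptor Csf1r -0.493 and Aif1 -0.466, with another Aif1 probe set at 0.02. C1qb had -0.282 without probiotic sample 2 and 0.193 with the Actb gap as a covariate, and the mean of the list with this covariate was -0.212. Neutrophil markers also fell as a set, with 4 of 5 measured genes lower and a mean of -0.665 (adjusted p = 0.021; adjusted p = 0.43 with an estimated correlation). S100a9, a calcium-binding protein of myeloid cells, was the only member past the test adjusted over the list alone (-1.55, SE 0.384). S100a8 had a difference of -1.07 (-0.493 without probiotic sample 1), the oxidase subunit Ncf1 -0.516 (-0.224 without probiotic sample 2, -0.335 without high-fat sample 1) and the antibody receptor Fcgr3a -0.347 (-0.212 without high-fat sample 1). The call for neutrophil markers was lost without the signal filter (adjusted p = 0.224), with array weights (0.0675), without probiotic sample 1 (0.103) and without high-fat sample 1 (0.0526). Without any of the other 4 samples, 4 measured genes remained, fewer than the 5 a list needs, and the list was not tested, so its call held with 0 of the 6 samples left out.

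Genes of bile acid synthesis and transport rose as a set, with 17 of 22 measured genes higher and a mean log2 difference of 0.259 (adjusted p = 0.005; adjusted p = 0.43 with an estimated correlation). No member passed on its own. The largest difference among the members named was that of Nr0b2, a nuclear receptor that represses bile acid synthesis, at 10.81 ± 0.935 against 8.89 ± 1.073 (SD, n = 3 each), or 3.79-fold more. Its log2 difference of 1.92 (adjusted p = 0.726 with limma) ranged from 1.32 (without high-fat sample 2) to 2.45 (without probiotic sample 1). The uptake transporter Slco1a4 had a difference of 0.617 (0.389 without probiotic sample 3, -0.01 with another probe set), the side-chain oxidase Acox2 0.564 and the racemase Amacr -0.413. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a difference of -0.347 (SE 0.793, adjusted p = 0.938), with probiotic values spread over an SD of 2.013. Its values were 9.934, 13.54 and 13.29 in probiotic samples 1, 2 and 3, and the difference was 0.815 without probiotic sample 1 and -0.988 without probiotic sample 2. The values of Cyp8b1, Cyp27a1, the bile acid receptor Nr1h4 and the export pump Abcb11 were 0.401, 0.257, 0.501 and 0.241. That of Abcb11 was 0.0134 without probiotic sample 3 or without high-fat sample 2, 0.432 without probiotic sample 2 and 0.534 without high-fat sample 1. The call for the list was lost without probiotic sample 3 (mean 0.126, adjusted p = 0.123). The levels of the list overlapped between groups, with probiotic sample 1 at -0.0315 and high-fat sample 1 at 0.029.

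Genes of fatty acid oxidation and targets of the receptor PPARalpha rose as a set, with 22 of 29 measured genes higher and a mean log2 difference of 0.224 (adjusted p = 0.00758; adjusted p = 0.778 with an estimated correlation). The peroxisome proliferation factor Pex11a had a difference of 0.695 (0.00 with another probe set), the peroxisomal enzyme Ehhadh 0.84, the lipid droplet protein Plin2 0.67 and the mitochondrial thiolase Acaa2 0.292, and no member passed on its own. Without probiotic sample 2 Ehhadh had 0.45 and Plin2 0.432, and another probe set gave 0.279 for Plin2 and 0.808 for Acaa2. Ppara itself, Cpt1a and Cyp4a1 had differences of -0.0764, 0.137 and 0.458, with another Cpt1a probe set at -0.733. Cyp4a1 had 0.216 without probiotic sample 2, 0.157 without high-fat sample 1 and 0.731 without high-fat sample 2. The sign of Ppara and of Cpt1a turned with the covariate (0.327 and -0.157) and without single samples. Ppara ranged from -0.361 (without probiotic sample 1) to 0.141 (without probiotic sample 3) and Cpt1a from -0.155 (without high-fat sample 1) to 0.346 (without probiotic sample 1). The mean was 0.339 without probiotic sample 3. The call was lost without probiotic sample 2 (mean 0.0681, adjusted p = 0.369), without high-fat sample 1 (0.16) or 3 (0.0853), and with the Actb gap as a covariate (0.696).

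**Figure D3:**
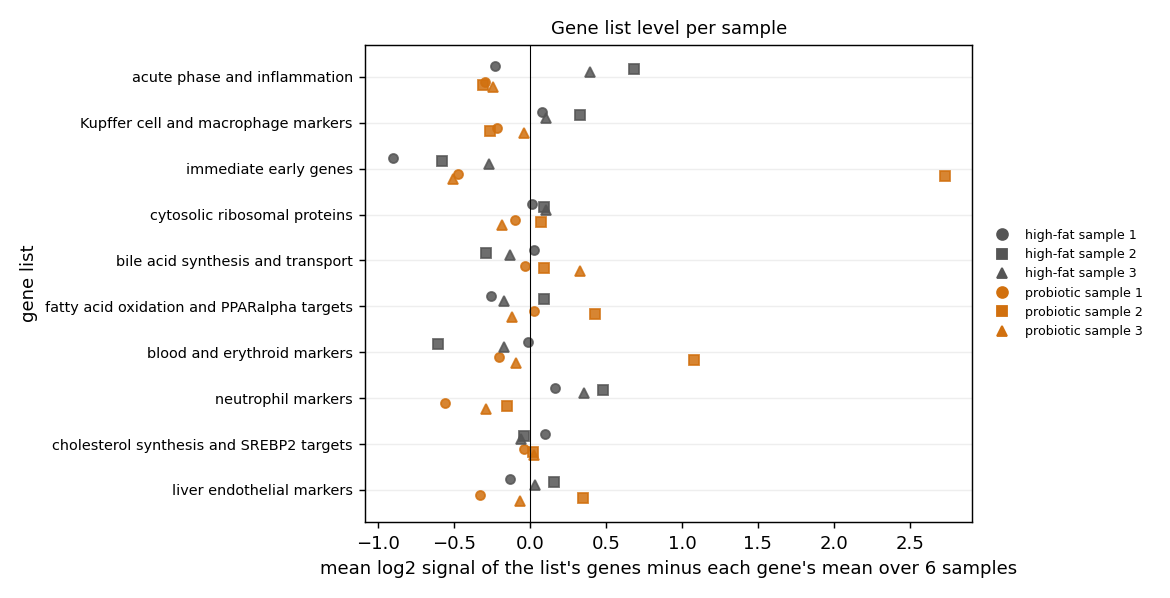
Mean log2 signal of the measured genes of each list after subtracting each gene's mean over the 6 samples (horizontal axis) for the 8 lists past the adjusted threshold and, for reference, cholesterol synthesis genes and endothelial markers; symbols give the sample number. Immediate early genes lay at 2.73 in probiotic sample 2 and below 0 in the other 5 samples.

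Immediate early genes, which respond within minutes to stimulation, were higher as a set through a single sample. Of 14 measured genes, 13 were higher, with a mean log2 difference of 1.17 (adjusted p = 0.000934; adjusted p = 0.778 with an estimated correlation), but all 14 had their highest value in probiotic sample 2. Without that sample the adjusted p was 0.866, and the median difference was 0.221 in place of 1.32. Egr1 had a difference of 2.31, Nr4a1 1.55, Gadd45b 1.87 and Klf6 1.40, none past the test, and with the Actb gap as a covariate the direction of the list turned (adjusted p = 0.00102). Without probiotic sample 2 Egr1, Gadd45b and Klf6 had 0.825, 0.704 and 0.33, and without probiotic sample 1 Gadd45b had 3.00. Other Klf6 probe sets gave 1.47 and 1.08. Blood and erythroid markers were higher as a set, with 6 of 7 measured genes higher and a mean of 0.527 (adjusted p = 0.0105; adjusted p = 0.778 with an estimated correlation). Beta-globin Hbb had a difference of 0.719, the heme synthesis enzyme Alas2 1.06, the platelet gene Pf4 0.943 and Bpgm 0.612 (1.06 with another probe set), none past the test. Without probiotic sample 2 these were 0.456, 0.505, 0.547 and 0.195. Bpgm had 0.383 without high-fat sample 2 and -0.0347 without both, and with the covariate Alas2, Pf4 and Bpgm had -0.07, -0.00123 and -0.395. The mean was 0.336 without probiotic sample 2 (adjusted p = 0.0583) and 0.357 without high-fat sample 2 (adjusted p = 0.087). The adjusted p was 0.311 without both and 0.122 with array weights, and the direction of the test turned with the Actb gap as a covariate (adjusted p = 0.176).

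Genes of cytosolic ribosomal proteins fell as a set by a small amount, with 17 of 17 measured genes lower and a mean log2 difference of -0.143 (adjusted p = 0.005; adjusted p = 0.778 with an estimated correlation). Rps16, Rpl3, Rpl6 and Rps6 had differences of -0.35, -0.348 (-0.19 with another probe set), -0.341 and -0.225, none past the test, and Rpl6 had -0.54, -0.174 and -0.226 without probiotic sample 2, probiotic sample 3 and high-fat sample 3. Without probiotic sample 3 the mean was -0.0842 (adjusted p = 0.178), and without probiotic sample 2 it was -0.216. With camera at the preset correlation 8 of 29 lists passed, 4 in each direction, and the mean of each kept its direction under median centring and without normalization between arrays. With an estimated correlation 0 passed, and with fry, which tests the lists on their own rather than against other genes, 0 passed.

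Genes of cholesterol synthesis did not pass the test as a set, with 9 of 19 measured genes higher and 10 lower (adjusted p = 0.664). Their mean log2 difference was 0.000485 and their median -0.0147, and the test pointed down. Insig1, which retains sterol sensors in the endoplasmic reticulum, had a difference of 1.70 (SE 0.72, adjusted p = 0.726), which was 0.845 without probiotic sample 2 and 2.61 without probiotic sample 1, and the sterol regulators Srebf2 and Srebf1 had -0.22 and -0.091. Squalene epoxidase, Sqle, lay below the signal filter and was not tested (-1.08). For the list of cholesterol efflux, uptake and lipoproteins the adjusted p was 0.351 (mean -0.145, or -0.0832 without probiotic sample 2), and 0.0458 under median centring. The sterol exporters Abca1, Abcg5 and Abcg8 had differences of -0.38, -0.28 and 0.0967, and the sterol receptor Nr1h3 had 0.209. Other probe sets gave 0.00313, -0.397 and -0.842 for Abca1 and 0.0265 for Srebf1. Apoa1, Apoa4 and Lpl had 0.0163, -0.578 and 0.0602, and the value for Apoa1 was -0.109 under median centring. The list of fatty acid and triglyceride synthesis had 11 genes higher and 12 lower (adjusted p = 0.981), with a mean of 0.00852 and a median of -0.0507. Fasn, the fatty acid synthase, had a difference of -0.683 (-0.236 without probiotic sample 2, -0.423 without high-fat sample 1, 0.0847 with another probe set) and the desaturase Scd -0.335. The Scd value was carried by probiotic sample 2, without which it was 0.761, and it was -0.991 without probiotic sample 1. None of these genes passed the test, and several signs did not hold. With the Actb gap as a covariate the values were 1.93 for Scd, 0.143 for Fasn, -0.0215 for Insig1, 0.231 for Srebf2, 0.122 for Srebf1, 0.06 for Abca1, 0.261 for Abcg5 and -0.223 for Lpl. Leaving out a single sample also turned the sign of Apoa4, which ranged from -1.10 (without probiotic sample 1) to 0.0463 (without probiotic sample 3), and of Abcg5 and Abcg8. Without high-fat sample 1 these had -1.07 and -0.354, and without high-fat sample 3 they had 0.311 and 0.399. With each sample left out in turn, Srebf2 ranged from -0.39 (without high-fat sample 3) to -0.0557 (without high-fat sample 2), Abca1 from -0.793 (without high-fat sample 1) to -0.134 (without high-fat sample 3) and Nr1h3 from 0.103 (without probiotic sample 1) to 0.382 (without probiotic sample 2). The differences of Srebf1, Apoa1 and Lpl were small and changed sign when single samples were left out.

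Antioxidant genes and metallothioneins had a mean log2 difference of -0.254 over 18 genes and an adjusted p of 0.0849 (0.43 with an estimated correlation, 0.198 with fry). Nqo1 was the only member past the test adjusted over the list alone. The list passed without probiotic sample 2 (adjusted p = 0.0256), without high-fat sample 1 (0.0274), under median centring (0.0221), without normalization (0.0271) and with the Actb gap as a covariate (0.0433), all at the preset correlation. Without high-fat sample 2 its mean was -0.168.

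Hepatocyte identity genes (mean 0.0727, adjusted p = 0.385), pericentral genes (0.0881, 0.531) and periportal genes (0.03, 0.664) did not pass. The hepatocyte identity mean was 0.0349 without probiotic sample 3 and 0.116 without probiotic sample 2. The pericentral mean ranged from -0.0255 (without probiotic sample 2) to 0.172 (without probiotic sample 1) and the periportal mean from -0.195 (without high-fat sample 1) to 0.17 (without high-fat sample 3). Periportal genes passed with the Actb gap as a covariate (0.0433). Among markers of other cell types, the mean and adjusted p were 0.143 and 0.351 for cholangiocytes, -0.0334 and 0.664 for stellate cells and matrix, -0.203 and 0.664 for B and plasma cells, and -0.00659 and 0.821 for T and NK cells, where the median was 0.172. The cholangiocyte mean was -0.0601 without probiotic sample 2 and 0.273 without probiotic sample 3 (adjusted p = 0.0578), and that of stellate cells -0.091 and 0.000749. That of T and NK cells was -0.269 without probiotic sample 1 and 0.0507 without probiotic sample 2, and that of B and plasma cells -0.363 without probiotic sample 1 and -0.0716 without high-fat sample 1. Endothelial markers had a mean of -0.0345 and an adjusted p of 0.664, which was 0.0304 without probiotic sample 2 (mean -0.216) and 0.00275 with the covariate; without probiotic sample 1 the mean was 0.122. Adipocyte and mesothelial markers had a mean of -0.0632, a median of 0.357 and an adjusted p of 0.981, with a mean of -0.26 without high-fat sample 3 and -0.00133 without high-fat sample 2.

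The remaining lists did not pass the test either. Oxidative phosphorylation genes had a mean log2 difference of -0.0834 (adjusted p = 0.282) and circadian clock genes 0.157 (adjusted p = 0.449), where the mean was -0.0378 without high-fat sample 1 and 0.42 without high-fat sample 3. Endoplasmic reticulum stress genes had a mean of 0.337 (adjusted p = 0.449), which rested on probiotic sample 2, without which it was -0.0859. The list passed without probiotic sample 1 (mean 0.695, adjusted p = 0.00296), and with the Actb gap as a covariate it passed in the opposite direction (adjusted p = 0.000479). The mean was -0.0449 for interferon response genes (adjusted p = 0.587) and -0.131 for sex-biased liver genes (adjusted p = 0.697). For glucose metabolism and insulin signalling the mean was 0.222 (adjusted p = 0.664), and for the cell cycle 0.167 (adjusted p = 0.773). Without probiotic sample 2 the means were 0.0388 for interferon response, -0.0459 for sex-biased genes, 0.099 for glucose metabolism and -0.0468 for oxidative phosphorylation. Without probiotic sample 3 they were -0.171 for interferon response (adjusted p = 0.0905) and -0.239 for sex-biased genes. The cell cycle mean was 0.0465 without high-fat sample 1 and 0.308 without high-fat sample 3, and that of oxidative phosphorylation -0.132 without high-fat sample 3. Xenobiotic metabolism had a mean of 0.0152 and a median of -0.0426 (adjusted p = 0.94, or 0.0433 with the covariate), with means from -0.0354 to 0.0928 when single samples were left out, and Cyp3a9 was its only member past the test adjusted over the list alone. In the other lists that did not pass, antioxidant genes aside, 0 members did.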

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

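No normalization, the Actb gap as a covariate and the removal of both sample 2 arrays were alternatives chosen after seeing the data. The count of probe sets past the adjusted threshold was 4, and 3 to 5 under most settings. It was 1 with the plain t-test, Nop56, which was 0 of the 4, and 3 to 12 with each sample left out in turn (12 without probiotic sample 1, 9 without high-fat sample 1, the other settings at 3 to 6). It was 6 without both sample 2 arrays, 3 of them among the 4. The count at unadjusted p under 0.05 and at least 1.5-fold was 1064 (473 higher, 591 lower). It was 1727 without the filter, 709 with a filter at the 60th percentile, 501 with the plain t-test, 483 at 2-fold or more, 616 without both sample 2 arrays, 432 with the covariate and 679 to 1574 with each sample left out (679 without probiotic sample 2 and 696 without high-fat sample 2). The more probe sets are tested, the more can be counted; otherwise the cause was not tested. Lists past the threshold numbered 8, 4 in each direction. With array weights 5 stayed, 2 higher and 3 lower, so blood markers were not the only higher list to lose its call. The count was 5 without both sample 2 arrays, 0 with an estimated correlation and 0 with fry. It was 5 to 8 with each sample left out (5 without probiotic sample 3). With the covariate 11 lists passed, and 3 directions turned: endoplasmic reticulum stress (adjusted p = 0.000479), immediate early genes (0.00102) and blood markers (0.176). The cause was not tested. The covariate also took xenobiotic (0.0433), periportal (0.0433) and endothelial (0.00275) lists past the threshold, and endoplasmic reticulum stress passed without probiotic sample 1 (0.00296). The robust variance model was not run for lists, since camera has no such option.

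The replicate numbers shared by the groups were tried as a block. Same-numbered samples correlated at 0.14, 0.027 and 0.077 in their deviations from the group means, so the numbers were not taken to pair the samples. Samples 1 and 3 correlated best with their own number and sample 2 did not. With the block there were 4 calls, 3 of the 4 and Stat3 (adjusted p = 0.00975), whereas 1377151_at had an adjusted p of 0.0896. The unadjusted count was 1183, and 9 lists passed, with antioxidant genes added (0.0167). The block changed no other call. Of 1403 recomputed values for 75 named genes and probe sets, 1338 stayed past the threshold or, where past it in neither setting, stayed within 1 SD. Another 47, past it in neither, moved further, 10 passed the threshold newly, 8 lost it and 0 called values changed sign. Signs changed in 48 values of genes that did not pass, 18 of them with the covariate. Probe sets near the floor, such as 1377151_at, lie at the limit of signal over background.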

Other observations

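Genes of the major histocompatibility complex, called RT1 in the rat, differed more than other genes of like signal. This family was examined after RT1-A and RT1-Ba were seen among the genes with lower signal, and both stay in the set. Over 28 probe sets of 18 RT1 genes, the median absolute log2 difference was 0.585, against 0.244 in the median of 10000 random sets matched on mean signal. In the probiotic group 23 probe sets were lower and 5 higher (20 and 8 under median centring, 21 and 7 without normalization), and 7 had an unadjusted p under 0.05, none past the adjusted threshold. RT1-A had a difference of -2.07, RT1-N2 of -1.85, and the antigen-loading genes RT1-DMa and RT1-DMb of -1.04 and -0.856. Of the 4 probe sets of the class II gene RT1-Ba, 1 had -1.21 and the others 1.67, 0.569 and 0.161.

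Median centring and leaving out each sample were planned before the data were examined. The tests of the RNA quality covariate and both tests on RT1 genes were set before their results were seen. The RT1 genes were chosen as a set only after RT1-A and RT1-Ba were seen to be lower. The tests without normalization, on the share of cell types and on other splits of the samples were chosen afterwards, as was what median centring and each left-out sample would have to show. For the 4 probe sets that fell, normalization between arrays is argued against, since 4 of the 4 stayed past the threshold under median centring and without normalization. RNA quality stays open, since the Actb gap did not overlap between the groups. A covariate on 6 arrays separates it from the group only through its spread within groups. The Gapdh gap did overlap, at 0.7106 in probiotic sample 1 and 0.7942 in high-fat sample 3. With the Actb gap as the covariate, 4 of the 4 were not nearer to 0 by more than 1 SE. The bound set in advance asked for 3 within 1 SE, and 1 met it because the other 3 moved away from 0, which that bound had not foreseen; 3 stayed past the threshold, and 1377151_at (-4.06, SE 0.413, against -3.71, SE 0.62) lost its call as its SE grew. Alleles spread at random would part as many probe sets by more than 2 log2 units in other splits as in the real one. The real groups parted 5, the 4 called probe sets among them, and any other split at most 1. The test was chosen after these 4 were seen to be parted, so it restates them and cannot count against such alleles. With 10 splits of 3 against 3 no share under 0.05 is possible either. The real split, 1 of 10, called 4 probe sets and the highest other 0. Random alleles are thus not excluded. An effect of the bacterium, untested otherwise, and inherited differences cannot be told apart.

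For the RT1 genes, a difference in alleles between the groups is a candidate explanation. The median absolute difference lay at percentile 100 of the matched random sets, as this needs. Those sets were matched on mean signal alone and do not share the sequence likeness of RT1 probe sets. The percentile thus cannot tell an allele difference between the groups from a family that varies between samples. The family was also picked after RT1-A and RT1-Ba were seen to be lower, so the percentile is no independent support. Variation between samples regardless of group stays open: the real split, 1 of 10, gave the highest median, 0.585, and the highest other was 0.484, so the test cannot decide it. A change in antigen-presenting cells is open too, as macrophage markers were lower in 17 of 17 genes (mean -0.343), among them the class II chaperone Cd74 (-0.345), and so is a change in histocompatibility gene expression with the bacterium.

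The acute phase and macrophage lists were lower together in the probiotic group. RNA quality stays open here too, since the Actb gap did not overlap between the groups. With the covariate the mean of the acute phase list went from -0.565 to -0.355 (SE 0.148 over members). It stayed below 0 by more than this SE, as the bound set in advance asked, but the members share the same 6 samples. High-fat sample 2 as the sole cause is argued against by -0.357 without it. What was left came mainly from high-fat sample 3 (0.393), as high-fat sample 1 (-0.229) lay near the probiotic samples. A lower share of all non-hepatocyte cells stays open: macrophage markers lay -0.309 (SE 0.0637 over genes) from the mean of 31 endothelial and stellate genes, but -0.154 (SE 0.0659) without probiotic sample 2 and 0.0198 (SE 0.0971) with the covariate. Less inflammation or fewer macrophages after the bacterium, as a hypothesis, and differences between samples in infection or handling both stay open, and the smallest camera p of the acute phase list in another split was 8.82e-08, against 4e-11.

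Immediate early genes had a median log2 difference of 1.32, and of 0.221 without probiotic sample 2. A chance arrangement of the samples is not excluded for the 1064 probe sets at unadjusted p under 0.05 and at least 1.5-fold, since 2 of 10 splits gave as many, the highest other at 1136, nor for the 8 lists, since 2 of 10 splits gave as many, the highest other at 8. Groups did not overlap in 2370 probe sets (12.72%), where chance gives 10%, and another split gave 2604.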
